A study of Mus musculus with 2 samples.

How the data were processed

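Droplet single-cell RNA sequencing was read from 2 libraries of sorted mouse lung epithelial cells, 1 per group. Per the labels, both mice were wild-type C57BL/6. The tumor-bearing mouse received 1000000 LLC cells carrying luciferase under the skin of the back and its lungs were taken at day 14, and the control mouse was untreated. Per the labels' protocols, lungs were digested with collagenase and DNase, and CD45-negative, SftpC-positive cells were sorted by flow cytometry to a stated purity above 95%. Per the series design, libraries were sequenced on an Illumina NovaSeq, and reads were processed with Cell Ranger 2.1.0 with default settings. Per the labels, the genome build was mm10, and R 3.5.3 and Seurat were also used, without a stated role. The authors deposited raw UMI counts per gene and barcode, not normalised. Each matrix held 737280 barcodes, so it was written before any call of cells. No cell annotation by the submitters was used here, so cells and classes were rebuilt and may differ from those of the submitters. Of the 28692 gene identifiers, 28339 (98.77%) were in the GENCODE vM21 annotation, from which coordinates were taken.

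Cells were called per library as barcodes with more UMIs than the 99th percentile of the 3000 largest barcodes divided by 10, the rule of Cell Ranger of that generation. The minimum was 3343 UMIs in the tumor-bearing and 2057 in the control library, which 7559 and 10969 barcodes passed. Barcodes with fewer than 500 genes (2 and 6) or more than 20% mitochondrial UMIs (0 and 12) were removed. Doublet scores were computed with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0 and 1 cells, under 0.5%, so the highest-scoring cells were removed up to 0.8% per 1000 called cells, which took out 457 and 959. Mixed droplets can remain after this step. The called barcodes held 87.4% and 86.5% of all UMIs. Empty droplets were barcodes with 1 to 100 UMIs, and held 5359717 and 2321211 UMIs.

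Both libraries were clustered together without integration, on log-normalised counts, 2000 variable genes chosen with library as batch, 30 principal components, 15 neighbours and Leiden resolution 0.5. Each cluster took the name of the marker class with the highest mean log2 fold over detected markers (at least 20 CPM and 3 UMIs) against the mean of the other clusters, with a pseudocount of 10 CPM. A cluster stayed unnamed with fewer than 3 detected markers, with more markers of another class among its 10 leading genes, with low UMI totals, or with AT2 markers raised beside those of another class. The marker lists were fixed before the data were examined, and this naming rule was set after the data were seen. Unnamed clusters carried AT2 markers with those of fibroblasts (6.16% of the tumor-bearing and 1.97% of the control library), platelets (1.13% and 2.34%), red cells (0.183% and 0.580%) or neutrophils (0.169% and 0.040%).

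Counts were summed over the cells of a class and scaled to CPM over all genes. Ratios are tumor-bearing over control, with a pseudocount of 1 CPM on the log2 scale, and fold values without one. Intervals are exact at 95%: Clopper-Pearson for shares, Poisson for CPM, and the conditional binomial interval for folds. The interval of a list median comes from Poisson redraws of the counts. A fold against 0 counts was taken from a floor of 3 counts over the whole control profile. With 1 library per group no test across mice was possible, so genes were described by a size rule: at least 50 CPM in either library, a log2 ratio of at least 1 in size and separate Poisson intervals. Gene lists were described by the median log2 ratio over members with at least 20 CPM in either library, and by its percentile among 10000 random lists of the same size matched on expression in 20 bins. A list with fewer than 3 measured members was given no median. There were 33 pathway lists and 23 marker lists fixed before the data were examined, and 3 lists added after it. The same was done for other classes with at least 100 cells in each library and for empty droplets. In simulated data with known differences, all 3-fold higher genes were called in the AT2-like, AT1-like and ciliated-like comparisons, 100%, 98.0% and 96.0% of 3-fold lower genes, and 0 unaltered genes. The intervals held the true fold for 95.0%, 95.3% and 95.8% of genes. Of genes with a 1.5-fold difference, 0% were called, and a list of unaltered genes lay at percentile 95.9, 80.2 and 25.1. The simulated data held counting error only, so they checked the calculation and not differences between mice or libraries.

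Genes were named by a rule fixed before the data were examined: in AT2-like cells, up to 12 genes per direction that met the size rule, leaving out genes whose CPM in the higher library was under 0.5 times that in its empty droplets, and up to 4 members per fixed list with the largest ratios. Of the genes that this rule names, 1 is not reported here. Other genes are named as chosen after their values were seen. Symbols absent from the files (Ca9, Ccn2, Cebpd, Cxcl11, Gucy1a1, Mx2 and Nectin2) were not analysed here. Coordinates are given for the genes of the size rule only.

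There were 13 alternatives fixed in advance: a minimum of 1000 or of 2000 UMIs in both libraries, a mitochondrial limit of 10% or none, no doublet removal, Leiden resolution 1.0, separate clustering, all called cells, cells thinned to 1000 UMIs, scaling by the median ratio, subtraction of free RNA by endothelial, red cell and leukocyte markers, a pseudocount of 10 CPM, and a lower CPM minimum. Another 4 were added after the data were seen: subtraction of free RNA by club markers, equal weight for the large AT2-like clusters, leaving out the AT2-like cluster led by Cxcl1 and immediate early genes, and including the mixed unnamed clusters. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.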

Results

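The comparison addresses how lung epithelial cells of a mouse carrying a tumor at a distant site differ from those of a mouse without one. Droplet single-cell RNA sequencing was available for 2 libraries of sorted mouse lung epithelial cells. The tumor-bearing library came from a mouse 14 days after 1000000 Lewis lung carcinoma cells (LLC, a transplantable mouse lung cancer line) were injected under the skin, and the control library from an untreated mouse. The libraries held 84448360 UMIs (unique molecular identifiers, each counting 1 captured transcript) in the tumor-bearing library and 91498124 in the control library. After filtering, 7100 cells of the tumor-bearing library and 9992 of the control library were kept. Their medians were 8855 and 6765 UMIs, 2030 and 1744 genes, and 2.98% and 3.35% mitochondrial UMIs. Each group had 1 library, so no difference given here has a replicate check, and a difference between the libraries could not be separated from one between the mice. All intervals are 95% intervals that cover counting error only. They are exact except for those of list medians, which come from Poisson redraws. Fold values are the tumor-bearing over the control library, and coordinates are on the mm10 build.

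Alveolar type 2 (AT2) cells, which make surfactant, were the main class in both libraries. AT2-like cells made up 77.7% (interval 76.8 to 78.7) of the tumor-bearing library and 86.5% (85.9 to 87.2) of the control library. Club-like cells, the secretory cells of the airway, made up 3.54% (3.12 to 3.99) of the tumor-bearing library and 0.751% (0.591 to 0.940) of the control library, a 4.71-fold ratio. Endothelial-like cells made up 4.92% (4.42 to 5.44) and 0.941% (0.761 to 1.15), a 5.22-fold ratio. Alveolar type 1 (AT1)-like cells, the flat cells of gas exchange, made up 2.87% (2.5 to 3.29) and 3.35% (3.01 to 3.73), and ciliated-like cells 2.73% (2.37 to 3.14) and 2.95% (2.63 to 3.30), with overlapping intervals. Basal-like cells made up 0.324% and 0.470%, and neuroendocrine-like cells 0.239% and 0.060%. Clusters without a name made up 7.63% and 4.93%, most of them droplets carrying fibroblast markers (6.16% and 1.97%) or platelet markers (1.13% and 2.34%) beside AT2 markers. Club-like and endothelial-like cells lie outside the stated CD45-negative, SftpC-positive sort, so their shares measured how each sort went as well as each lung. The smallest UMI total of a called cell also differed, 3343 against 2057. With an equal minimum of 1000 or 2000 UMIs the endothelial-like shares were 9.33% against 1.18% and 7.05% against 0.659%. With each library clustered on its own the endothelial-like share was 3.31% against 0%, while the club-like share of the control library was 2.14% and that of the tumor-bearing library stayed within its interval.

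**Figure D1:**
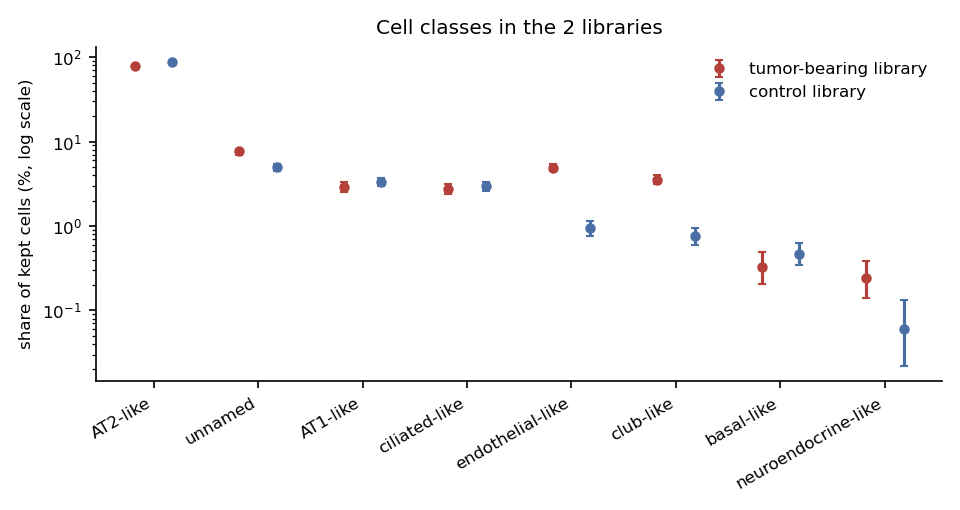
Share of kept cells (percent, log scale) in each cell class, with 1 point per library and exact 95% binomial intervals as bars. Club-like cells stood at 3.54% in the tumor-bearing and 0.751% in the control library, and endothelial-like cells at 4.92% and 0.941%.

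Among genes with at least 50 CPM in AT2-like cells of either library, Acot1, which encodes an acyl-CoA thioesterase, stood furthest above the control level. Its level was 118 CPM (UMI counts scaled to a common library total) in the tumor-bearing library and 44.4 CPM in the control library, a 2.65-fold ratio (2.53 to 2.77). The gene (ENSMUSG00000072949) lies on chromosome 12 at 84009490 to 84018371. Dbp, a transcription factor driven by the circadian clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), was 2.03-fold higher (1.97 to 2.09), at 239.8 against 118 CPM. Vpreb3 (ENSMUSG00000000903, chromosome 10, 75943057 to 75949657), known from the pre-B cell receptor, stood at 0.446 times the control level (0.424 to 0.468), 42.3 against 94.9 CPM. These were 3 of the 4 genes that met the 2-fold rule among 1767 genes with at least 50 CPM in either library, with 3 genes higher and 1 lower. The remaining one was Scgb1a1, the main secretory transcript of club cells, at 6294 against 2527 CPM and a 2.49-fold ratio. Its level in AT2-like cells was only 5.51% of that in empty droplets of the tumor-bearing library and 18% in the control library, so it was left out of the named genes by the rule on free RNA, and whether AT2 cells also express it stays open. Among the list members named for AT2-like cells, Ifitm3, Hspa1a, Klf2, Hp, Bpifa1, Cav2, Hopx, Vegfa, Cryab and Mt2 also lay under 0.5 times their empty droplet level in the library where they were higher, and free RNA is not excluded for them.

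The AT2-like profiles lay close together, from 5520 and 8647 cells with 50843394 and 61000759 summed UMIs. The median log2 ratio over the 1767 genes was -0.055, and 95% of genes lay between -0.37 and 0.36. A ratio of at least 1.5-fold was seen for 13 genes higher and 15 lower. The largest AT2-like cluster of the tumor-bearing library was led by Lyz1, Bex2 and Napsa. That of the control library was another, led by Nrn1, Scd1 and Apoc1. The former held 2370 cells of the tumor-bearing and 231 of the control library, and the latter 310 and 3659. The AT2-like profiles thus sum unlike mixes of clusters. Another AT2-like cluster was led by Areg, Gsta1 and MHC class II genes, another by Cxcl1, Areg and the immediate early gene Egr1, and a small one by the cell division genes Stmn1 and Top2a. Inside each of the 4 large AT2-like clusters the sign was the same for Acot1 (log2 ratio 1.22 to 1.71), Dbp (1.00 to 1.08) and Vpreb3 (-1.21 to -0.73). Bex2, chosen after its values were seen, was 1.78-fold higher (1.74 to 1.82) over all AT2-like cells.

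Genes of fatty acid synthesis were lower in AT2-like cells of the tumor-bearing library. The desaturase genes Scd2 and Scd1 stood at 0.523 (0.512 to 0.535) and 0.662 times the control level, and Srebf1, a transcription factor of lipid synthesis, at 0.684 times. The median log2 ratio of the 16 measured list members was -0.23 (-0.26 to -0.16), at percentile 0.00 of 10000 random lists matched on expression, and 10 of the 16 were below 0. Within the large AT2-like clusters the list median was -0.039 in the largest one of the tumor-bearing library and -0.26 to -0.25 in the other 3, while Scd2 lay between -0.95 and -0.87 in all 4. Without the CPM minimum the list median was -0.07. Elovl1, which elongates fatty acids, went the other way at 1.34-fold. Cholesterol synthesis had no direction, with a median of 0.009 and 9 members above and 7 below 0. In that list Insig1 was lower (0.782 times), and Msmo1 (1.18-fold) and Hmgcs1 (1.15-fold) were higher. In ciliated-like cells the fatty acid synthesis median was -0.246 (-0.419 to 0.006), at percentile 0.13 of random lists. Scd2 stood there at 0.471 times, below 0.5 times its empty droplet level. In AT1-like cells the fatty acid synthesis median was -0.034, at percentile 92.55, while Scd2 stood at 0.628 times.

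Genes of fatty acid oxidation, a list chosen after Acot1 was seen, were higher in AT2-like cells of the tumor-bearing library. Acadl, a mitochondrial acyl-CoA dehydrogenase, was 1.92-fold higher (1.83 to 2.00). Acot2, a paralog of Acot1 beside it on chromosome 12, was 1.80-fold higher, Eci2 1.66-fold, the carnitine carrier Slc25a20 1.65-fold and the lipid droplet gene Plin2 1.63-fold. The median log2 ratio of the 24 measured members was 0.31 (0.28 to 0.34), at percentile 100 of the random lists, and 20 of the 24 were above 0. Acot1 itself is among these members, so the median, percentile and count are a description and not separate support. Hadhb (0.914 times) and Echs1 (0.871 times) were lower. The median was 0.043 in AT1-like cells, at percentile 99.2 and against -0.18 for all their genes, and 0.15 in ciliated-like cells, at percentile 96.2. The single members named in this paragraph were chosen after their values were seen.

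MHC class I genes, which present peptides to T cells, were lower in AT2-like cells of the tumor-bearing library. B2m stood at 0.534 times the control level (0.525 to 0.543), 402 against 753 CPM. H2-K1 stood at 0.587 times, H2-Q4 at 0.668 times and H2-Q6 at 0.402 times, and the list median over 12 members was -0.23 (-0.29 to -0.18), with 10 below 0. MHC class II differed less, with a median of -0.088, at percentile 27.2 of random lists. H2-Eb1, H2-Aa and H2-Ab1 stood at 0.908, 0.933 and 0.936 times the control level, while H2-DMb1 was 1.11-fold higher. In ciliated-like cells the class I median was -0.245 (-0.464 to -0.032), at percentile 0.35 of random lists, with B2m at 0.664 times. In AT1-like cells it was -0.199, at percentile 28.3 and against -0.18 for all their genes, with B2m at 0.878 times.

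Inflammatory and interferon genes were mixed. Among 6 measured chemokine and cytokine genes, Cxcl2 was 3.84-fold higher (3.49 to 4.22), Cxcl1 1.97-fold and Il33 1.25-fold, while Cxcl16 stood at 0.921 times; the median was 0.14 (0.099 to 0.20). The log2 ratio of Cxcl2 ran from 0.15 to 2.00 between the 4 large clusters, and it was 0.67 over AT2-like cells without the cluster led by Cxcl1 and immediate early genes, while that of Cxcl1 was 0.25 with separate clustering. Only 5 interferon response genes were measured, with a median of 0.20 (0.10 to 0.29). Ifi27l2a was 2.72-fold (2.48 to 2.99) and Ifitm3 2.06-fold higher, Irf1 1.15-fold, and Bst2 stood at 0.914 times. Ifitm3 reached 298 CPM in empty droplets of the tumor-bearing library against 47.6 CPM in its AT2-like cells, and its log2 ratio was 0.27 after subtraction of free RNA by endothelial, red cell and leukocyte markers. Neither leading gene was higher inside the largest AT2-like cluster of the tumor-bearing library (log2 ratio -0.33 for Ifi27l2a and -0.02 for Ifitm3). The interferon median turned negative with a mitochondrial limit of 10% (-0.002), with each library clustered on its own (-0.035) and without the cluster led by Cxcl1 and immediate early genes (-0.11). NF-kB targets had a median of 0.046, which turned to -0.024 with separate clustering. Nfkbia was 1.40-fold, Nfkbiz 1.39-fold and Birc3 1.13-fold higher, and Traf1 stood at 0.901 times. The log2 ratio of Nfkbia ran from 0.011 to 0.539 between the alternatives. It was 0.61 in the cluster led by Cxcl1 and immediate early genes, but -0.05 to 0.14 in the other large clusters. Pattern recognition genes had a median of -0.12 over 3 members, with Myd88 at 0.879, Irf3 at 0.920 and Ager at 1.07 times the control level.

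Immune regulation genes were higher, with a median of 0.37 over 4 members. Ptgs2, the inducible prostaglandin synthase, was 1.48-fold, Lgals9 1.35-fold and Cd200 1.24-fold higher, and Cd47 stood at 0.926 times. The log2 ratio of Ptgs2 ran from 0.015 to 0.604 between the alternatives. It was -0.46 in the largest AT2-like cluster of the control library. Without the CPM minimum, which admits weakly expressed members, that median was -0.063. Acute phase and complement genes had a median of 0.24 over 8 members, with Lrg1 1.53-fold, the iron-binding Lcn2 1.37-fold and Hp 1.23-fold higher. Bpifa1 was 3.97-fold higher, yet its level in AT2-like cells was 4.57% of that in empty droplets of the tumor-bearing library. Inside the largest AT2-like cluster of the tumor-bearing library the log2 ratio was 0.306 for Lrg1, but 0.045 for Lcn2 and 0.007 for Hp. Of the genes assigned to the pre-metastatic niche, only Vegfa (0.863 times) and Hmgb1 (1.07-fold) passed the CPM minimum, so no median was taken.

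AT2 identity genes were slightly higher in AT2-like cells of the tumor-bearing library. The chemokine-like Cxcl15 was 1.46-fold, Lyz1 1.44-fold, Egfl6 1.24-fold and Chil1 1.22-fold higher, and the median over 21 members was 0.083 (0.073 to 0.085), with 14 above 0. Over all called cells without classes that median was -0.045. Inside the large AT2-like clusters the log2 ratios of Cxcl15, Lyz1, Egfl6 and Chil1 were all above 0. They reached at most 0.526 for Cxcl15 and 0.413 for Lyz1, below 0.549 and 0.531 over all AT2-like cells. Chil1 ran from 0.079 to 0.294 and Egfl6 from 0.253 to 0.339, against 0.286 and 0.305 over all AT2-like cells. The mix of clusters may therefore add to the ratios of Cxcl15 and Lyz1. The transitional state between AT2 and AT1 cells had a median of -0.14 (-0.17 to -0.092), with Krt8 at 0.842 and Krt19 at 0.820 times the control level. With the large AT2-like clusters weighted equally that median was 0.022. Areg (1.85-fold) and Hbegf (1.27-fold), both ligands of the epidermal growth factor receptor, were higher over all AT2-like cells. Areg was lower (log2 ratio -0.22) in the largest AT2-like cluster of the control library, and with separate clustering its log2 ratio was 0.30 and that of Hbegf -0.053. AT1 genes had no direction (median -0.003), with Hopx at 0.751 and Vegfa at 0.863 times, Cav2 at 1.16-fold and Lmo7 at 1.10-fold, and both Hopx (0.30) and Vegfa (0.26) turned positive after subtraction of free RNA by club markers. Epithelial adhesion genes had a median of -0.091, at percentile 22.1 of random lists. Jup stood at 0.731, Krt7 at 0.811 and Dsp at 0.863 times, while Epcam was 1.19-fold higher. Tgfbi (1.25-fold) and Sparc (1.10-fold) were the 2 measured mesenchymal genes.

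**Figure D2:**
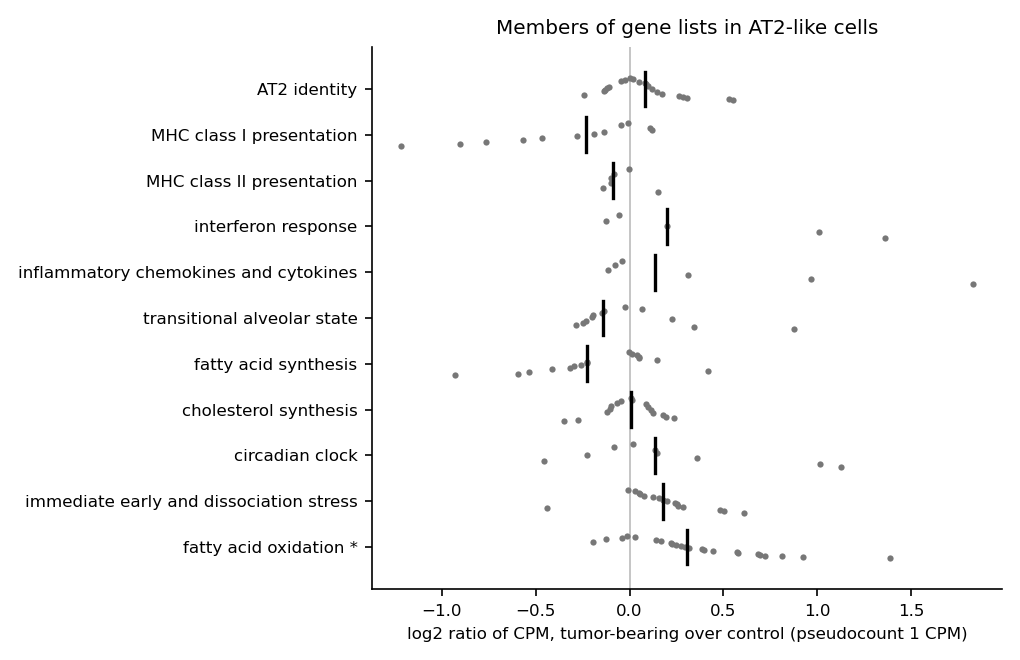
Log2 ratio of CPM in AT2-like cells (tumor-bearing over control, pseudocount of 1 CPM) for the measured members of 11 gene lists, 1 grey point per gene and a black line at the list median. Fatty acid oxidation, marked with an asterisk as chosen after the data were seen, had its median at 0.31, and fatty acid synthesis and MHC class I at -0.23.

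Several clock and immediate early genes were higher in AT2-like cells of the tumor-bearing library, while heat shock genes were mixed. The clock repressor Nr1d1 was 2.28-fold (2.09 to 2.49) and Per1 1.29-fold higher, Bhlhe40 stood at 0.722 times, and the clock list median was 0.14. Between the alternatives the clock list median ran from 0.018 to 0.193. Hspa1a was 3.14-fold higher (2.91 to 3.39), with 122 CPM in empty droplets of that library against 47.5 CPM in its AT2-like cells, Dnajb1 1.41-fold and Dnaja1 1.30-fold, while Cryab stood at 0.719 times. The heat shock median was 0.083, with 6 members above and 4 below 0, and -0.025 over all called cells. Jun, Klf6 and Klf2 were 1.42-fold, 1.40-fold and 1.55-fold higher and Socs3 stood at 0.733 times, with an immediate early median of 0.18 and 15 of 17 members above 0. With each library clustered on its own that median was -0.077, and without the Cxcl1-led cluster -0.008. The immediate early list was fixed as one of immediate early and dissociation stress genes. A difference in the handling of the lungs could not be separated from other causes. The glucocorticoid target Zbtb16 was 2.13-fold higher. The metallothionein genes Mt2 and Mt1, which also answer to metals and oxidants, stood at 0.279 (0.248 to 0.313) and 0.603 times. The log2 ratio of Mt1 was -1.06 in the cluster led by Cxcl1 and immediate early genes. It was only -0.051 in the largest AT2-like cluster of the control library. Over the 4 large clusters Mt2 ran from -2.364 to -0.737. The glucocorticoid median was 0.058. The oxidative stress median was -0.099, at percentile 12.6 of random lists, with Prdx6 at 0.818 and Sod2 at 0.822 times.

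Genes of energy metabolism were at or slightly below the level of other genes in AT2-like cells of the tumor-bearing library. All 12 mitochondrially encoded genes were below 0 (median -0.21), led by mt-Nd3 at 0.744 times the control level, but after subtraction of free RNA by club markers the list median was -0.003. The 10 glycolysis genes were below 0 (median -0.15, percentile 1.81 of random lists), with Hk2 at 0.777 and Pkm at 0.849 times. The 38 nuclear genes of the respiratory chain were below 0 as well (median -0.088, Cycs at 0.858 times), but at percentile 7.38, close to the median of -0.055 for all genes. Hypoxia genes had a median of -0.21, with P4ha2 at 0.801 and Higd1a at 0.858 times, while P4ha1 was 1.17-fold higher, and the median was -0.063 after subtraction of free RNA by club markers. Ribosomal protein genes had a median of -0.081, at percentile 16.8 of random lists, with Rpl5 at 0.864 and Rplp1 at 0.865 times. The unfolded protein response had a median of -0.037, which became 0.015 under scaling by the median ratio, with Sdf2l1 at 0.611 and Xbp1 at 0.803 times and Dnajb9 1.14-fold higher.

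**Figure D3:**
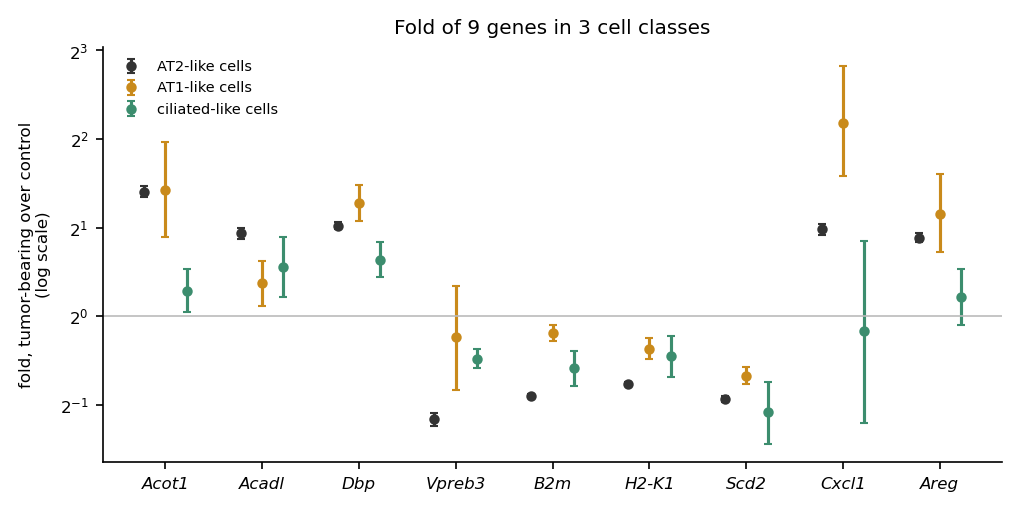
Fold (tumor-bearing over control, log scale) of 9 genes in AT2-like, AT1-like and ciliated-like cells, with exact 95% counting intervals as bars. In AT2-like cells Acot1 stood at 2.65-fold, Dbp at 2.03-fold and B2m at 0.534 times the control level.

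Growth and division genes differed in both directions in AT2-like cells. Ccnd1 was 1.48-fold and Stmn1 1.33-fold higher, the latter with log2 ratios of 0.04 to 0.32 within the large clusters. Stmn1 also leads the small cluster of cell division genes. That cluster made up 0.493% (0.344 to 0.685) of the tumor-bearing and 0.190% (0.115 to 0.297) of the control library, from 35 and 19 cells. Stmn1 itself differs between the libraries, and the cause of the unequal shares was not tested. The 4 measured cell cycle genes were all above 0, with a median of 0.27, which was 0.072 with separate clustering. The Notch target Hes1 stood at 0.645 times the control level and Bambi was 1.37-fold higher in a signalling target list with a median of -0.24 over 4 members, which was 0.01 over all called cells. The growth factor list had no direction (median -0.029), with Pdgfa at 0.857 times. The p53 target Bbc3 stood at 0.569 times and Cdkn1a at 0.900 times. Their list had a median of -0.11, at percentile 30.6 of random lists. Lysosome genes had a median of 0.081, with Cd63 and Lgmn 1.12-fold higher. Xist, the transcript of the inactive X chromosome, was present in both libraries, at 649.9 and 781 CPM.

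AT1-like cells of the tumor-bearing library carried more endothelial and AT2 transcripts than those of the control library. Plvap was 4.49-fold, Tmem100 3.15-fold and Cldn5 2.67-fold higher, all endothelial markers, and the AT2 marker Cxcl15 was 2.48-fold higher. Of 2952 genes, 65 were at least 2-fold higher and 5 lower, from 204 and 335 cells. The median over all genes was -0.18, so these ratios lie above that shift. Of the 65 genes, 8 were on the endothelial marker list and 4 on the AT2 list, and 54 stood above 0.5 times their level in empty droplets. Tmem252, Gpihbp1, Foxf1, Aqp1 and Ly6c1, not on that endothelial list, were also among the 65 and among the leading genes of the endothelial-like cluster. Passing the empty droplet limit therefore does not make a gene one expressed by AT1 cells. Ccl21a, a lymphatic endothelial marker, had 317 UMIs against 0. Lrg1 was 5.04-fold (3.79 to 6.79) and Ifitm3 3.58-fold higher, at 126 and 305 CPM, against 243 and 298 CPM in empty droplets of that library. Socs3 was 2.06-fold higher, and the clock genes Dbp, Nr1d1 and Per1 were 2.42-fold, 2.35-fold and 2.23-fold higher. Retnla stood at 0.053 times the control level (0.024 to 0.104), from 9 and 198 UMIs. The AT2 identity list had a median of 0.78 in these cells and AT1 genes -0.19. The genes named for AT1-like and ciliated-like cells were chosen after their values were seen.

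Ciliated-like cells of the tumor-bearing library had lower levels of immediate early and dissociation stress genes. Socs3 stood at 0.245 times the control level, Nr4a1 at 0.350, Atf3 at 0.371, Junb at 0.436 and Egr1 at 0.499 times. The metallothionein genes Mt1 and Mt2 stood at 0.469 and 0.326 times. Of 3188 genes, 9 were at least 2-fold higher and 31 lower, from 194 and 295 cells, with a median over all genes of 0.027, and 9 of the 31 belonged to the immediate early list. The hemoglobin genes differed more, with Hbb-bs at 0.088 times, Hba-a1 at 0.041 times and Hba-a2 at 0.042 times (0.009 to 0.128, from 3 and 83 UMIs), all below 0.5 times their empty droplet level. Reg3g, which encodes an antibacterial lectin, had 85 UMIs against 2 and a ratio of 49.8-fold (13.4 to 418). It stood at 70.7 against 1.42 CPM in ciliated-like cells and at 40.5 against 0.862 CPM in empty droplets. Transcripts of other cells are therefore not excluded for it. Ifitm1 was 3.31-fold higher (2.78 to 3.95) and Ccnd2 2.04-fold. Scgb1a1 and Scgb3a2 were 2.82-fold and 2.52-fold higher, and both lay below 0.5 times their empty droplet level. The cholesterol synthesis list had a median of 0.53 in ciliated-like cells.

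Empty droplets, barcodes with 1 to 100 UMIs that hold free RNA, contained more club and endothelial transcripts in the tumor-bearing library. Scgb1a1 made up 114315 CPM there against 14043 CPM in the control library. The endothelial marker Cldn5 was 9.10-fold higher (6.66 to 12.8) and Plvap 6.85-fold, both chosen after their values were seen. Of 1892 genes, 41 were at least 2-fold higher and 4 lower, with a median over all genes of -0.11. These droplets held 6.35% of the UMIs of the tumor-bearing library and 2.54% of the control library. By 3 marker sets, estimates of free RNA in the UMIs of AT2-like cells were 5.48% to 10.6% in the tumor-bearing and 16.3% to 19.2% in the control library. These are upper estimates, since single markers gave less. In AT2-like cells of the tumor-bearing and control libraries, Hbb-bs stood at 2.00% and 5.63% of its empty droplet level. Scgb3a2 stood at 3.68% and 6.28%. Lcp1, of the leukocyte markers, stood at 114% in both, more than free RNA can give. Values after subtraction of free RNA may therefore be overcorrected.

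**Figure D4:**
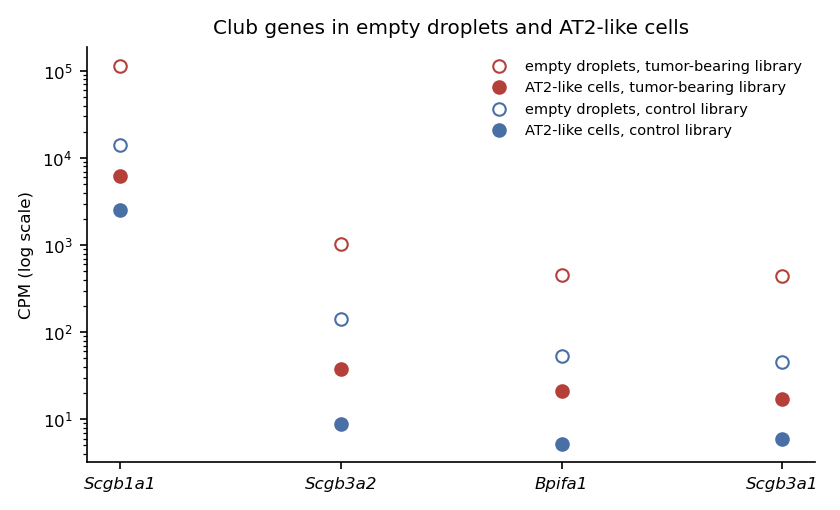
Level (CPM, log scale) of 4 club genes in empty droplets (open circles) and in AT2-like cells (filled circles) of each library. In AT2-like cells each gene lay at 3.68% to 5.51% of its empty droplet level in the tumor-bearing library and at 6.28% to 18% in the control library.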

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

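Of the tests in this part, the pair on club transcripts was written before its result was seen, and the comparisons between cell classes were chosen as patterns only after their values were seen.

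Some gene lists had opposite signs in different cell classes. Immediate early and dissociation stress genes had a median log2 ratio of 0.69 in AT1-like cells and -1.01 in ciliated-like cells. Glucocorticoid response genes had 0.60 in AT1-like and -0.32 in ciliated-like cells. MHC class II genes had 0.22 in AT1-like and -0.44 in ciliated-like cells, and the AT1-like value turned negative in 6 of the 7 settings that redrew the cells or clusters (-0.18 with a minimum of 1000 UMIs, for example). Hypoxia genes had -0.21 in AT2-like cells, 0.24 in AT1-like and 0.22 in ciliated-like cells. The sign in ciliated-like cells is not secure: the counting interval ran from -0.26 to 0.38, and the median was -0.20 without doublet removal and -0.16 without the CPM minimum. AT1-like cells of the tumor-bearing library also carried more AT2 and endothelial markers (medians 0.79 and 1.63), against a median of -0.18 over all their genes, so transcripts of other cells are mixed into their values. These differences between classes were not tested, since each class had 1 value per library.

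Empty droplets, which served the comparisons of cells only as a background, held more club transcripts in the tumor-bearing library. Scgb1a1 was 8.14-fold higher, Scgb3a2 7.30-fold, Bpifa1 8.63-fold and Scgb3a1 9.87-fold. The same 4 genes were higher in AT2-like cells, Scgb1a1 by a log2 ratio of 1.32. With free RNA as the cause, the genes would keep about 1 ratio to the empty droplets. In the tumor-bearing library the highest share of the 4 was 1.495 times the lowest, which met the prediction for free RNA. In the control library the shares were more uneven, from 6.28% to 18%. The result covers these 4 genes only. Of the other club markers in the tumor-bearing library, Cldn10 (4.84%) and Gabrp (5.53%) lay close to them. Cyp2f2 stood at 10.2%, and Hp, Retnla, Aldh1a7 and Cbr2 at 45.7% to 108%. The red cell gene Hbb-bs stood below all 4, at 2.00%, so free RNA as their whole source was not shown. Own expression in a subset of AT2 cells stays open: the upper 1% of thinned AT2-like cells held 10.8% of the Scgb1a1 UMIs in the tumor-bearing library, between the bounds set in advance. In the control library the upper 1% held 22.2%, so these UMIs were less concentrated in the library where Scgb1a1 was higher. The larger club-like share may have supplied the RNA, or the sort and wash may have differed.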

How the results depend on the processing

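The 13 alternatives without a mark were chosen before the data were examined, and the 4 marked as added after it. No paired analysis was possible because there was 1 library per group. In every setting that gave shares, the AT2-like share was lower and the club-like and endothelial-like shares were higher in the tumor-bearing library. In all 17 alternatives the log2 ratio kept its sign for Acot1 (1.21 to 1.48), Dbp (0.92 to 1.07), Vpreb3 (-1.38 to -0.93), Scd2 (-1.02 to -0.88) and B2m (-1.02 to -0.63), and so did the medians of fatty acid oxidation (0.22 to 0.36), fatty acid synthesis (-0.30 to -0.07) and MHC class I (-0.29 to -0.13). Of the values of single genes, 1827 stayed within their counting interval, 597 moved outside it and 24 changed sign, and of the other list medians 404, 118 and 17. Shares are given as tumor-bearing, then control. Except where a reason is given, the cause was not tested. Depth limits the AT1-like and ciliated-like values, with 204 and 194 cells in the tumor-bearing library, and lists with few members over the CPM minimum.

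With a minimum of 1000 UMIs, the shares were 72.9% and 84.9% (AT2-like), 3.74% and 5.18% (AT1-like), 9.33% and 1.18% (endothelial-like), and 1.10% (club-like, control). AT1-like cells had 43 genes higher and 3 lower and an MHC class II median of -0.18. With a minimum of 2000 UMIs, the AT2-like shares were 65.3% and 76.0%, as a cluster led by Areg and Cxcl1 stayed unnamed. The endothelial-like shares were 7.05% and 0.659%, the control club-like share 1.19%, the interferon median 0.094, the AT1-like genes lower 3 and the AT1-like MHC class II median -0.09.

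With a mitochondrial limit of 10%, the AT2-like shares were 63.9% and 71.7%, as a cluster led by Areg stayed unnamed, and the endothelial-like shares 3.04% and 0.634%. The control shares were 4.24% (AT1-like) and 1.18% (club-like). Medians changed sign for interferon (-0.002), NF-kB targets (-0.003) and AT1-like MHC class II (-0.12), as did Irf1 (-0.002), and 1 gene was lower in AT1-like cells. With no such limit, the control shares were 85.7% (AT2-like), 4.10% (AT1-like) and 1.17% (club-like), with 3 genes lower in AT1-like cells and an MHC class II median of -0.15 there. Without doublet removal, the control AT2-like share was 85.0%, the AT1-like shares 3.32% and 4.89% and the endothelial-like shares 2.77% and 0.557%, with 43 genes higher and 2 lower in AT1-like cells and an MHC class II median of -0.31 there.

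At Leiden resolution 1.0, the AT2-like shares were 73.4% and 80.0%, as a cluster of AT1 and AT2 markers stayed unnamed, the control club-like share 1.14%, and the MHC class II median -0.077 in AT2-like and -0.26 in AT1-like cells. With each library clustered on its own, the AT2-like shares were 63.8% and 73.8%, as clusters with neutrophil or AT1 markers stayed unnamed, the endothelial-like shares 3.31% and 0%, and the control club-like share 2.14%. The inflammatory median was 0.091, and the sign changed for interferon (-0.035), NF-kB targets (-0.024), immediate early genes (-0.077), Hbegf (-0.053), Irf1 (-0.15), Birc3 (-0.063) and Hmgb2 (-0.005).

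Over all called cells, which adds the other cell types, 20 genes were higher and 5 lower. Medians were -0.045 (AT2 identity), -0.21 (MHC class II), -0.025 (heat shock) and 0.01 (signalling targets), and the sign changed for Bst2 (0.061), Ager (-0.15), Cd47 (0.019), Prdx6 (0.029), Cdkn1a (0.25), Sparc (-0.012) and Psap (0.071). With the lower CPM minimum, which admits more genes, 21 were higher and 11 lower in AT2-like cells, 226 and 51 in AT1-like and 59 and 57 in ciliated-like cells. Medians were -0.005 (transitional state), 0.06 (inflammatory), 0.013 (interferon), -0.063 (immune regulation), -0.023 (heat shock) and 0.022 (signalling targets). With a pseudocount of 10 CPM, which shrinks the ratios of weak genes, 1 gene was lower in AT1-like cells and 5 higher in ciliated-like cells.

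With cells thinned to 1000 UMIs, 2 genes were lower, the medians were 0.064 (AT2 identity), -0.045 (transitional state), 0.29 (interferon) and -0.065 (MHC class II), and the sign changed for Cd47 (0.018) and Ctsa (-0.004). Scaling by the median ratio, which shifts the log2 ratios up and can take a member under the CPM minimum, gave 0.14 (AT2 identity), -0.09 (transitional state), 0.37 (inflammatory), -0.036 (MHC class II) and 0.015 (unfolded protein response), with 1 gene lower in AT1-like cells. With free RNA subtracted by endothelial, red cell and leukocyte markers, 3 genes were lower, the interferon median was 0.079, Vegfa had 0.048, and Scgb1a1 -8.17, since the subtraction took out nearly all of its counts. With free RNA subtracted by club markers (added), the medians were 0.064 (AT2 identity), -0.06 (transitional state), 0.34 (interferon) and -0.12 (MHC class II), with Hopx at 0.30, Vegfa at 0.26 and mt-Co3 at 0.008.

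With the large AT2-like clusters weighted equally (added), 0 genes were lower, the medians were 0.052 (AT2 identity), 0.022 (transitional state), 0.093 (interferon) and -0.04 (MHC class II), and the sign changed for Cxcl16 (0.068) and Hmgb2 (-0.037). Without the cluster led by Cxcl1 and immediate early genes (added), the medians were 0.079 (inflammatory), -0.11 (interferon), -0.001 (NF-kB targets), -0.14 (MHC class II) and -0.008 (immediate early), and the sign changed for Irf1 (-0.19), Birc3 (-0.03) and Dnajb9 (-0.024). With the mixed unnamed clusters included (added), 6 genes were higher and 4 lower, and the medians were 0.065 (AT2 identity) and -0.096 (MHC class II).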

Other observations

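All tests in this part were chosen only after the result was seen, and so was the fatty acid oxidation list.

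Neutrophil transcripts were present in the empty droplets of the tumor-bearing library and nearly missing from those of the control library. S100a8 stood at 487 CPM from 2609 UMIs, against 0.862 CPM from 2 UMIs, a ratio of 565-fold (156 to 4668). S100a9 had 1876 UMIs against 0, at least 271-fold higher, Ngp was at least 67.4-fold and Camp at least 47.4-fold higher, each from a floor of 3 control UMIs (1.29 CPM). The lower limits of their exact intervals were smaller, at 220-fold, 54.6-fold and 38.3-fold. A cluster led by these genes held 12 cells of the tumor-bearing and 4 of the control library. The stated CD45-negative sort would remove neutrophils, and these genes were chosen after their values were seen.

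Higher fatty acid oxidation genes in AT2-like cells were weighed against technical causes. Subtracting free RNA left the list median at 0.32, which argues against free RNA as the whole cause. The lowest value within a large AT2-like cluster was 0.27. The libraries were clustered together without integration, and the clusters were unevenly filled. The largest one of the tumor-bearing library held 2370 of its cells and 231 of the control library, and that of the control library 310 and 3659. Another mix of cells therefore cannot be fully separated from a shift between the libraries. Another time of day is a candidate explanation: clock genes of the Dbp phase minus those of the opposite phase gave 0.37 in AT2-like, 1.72 in AT1-like and 0.70 in ciliated-like cells. Unlike the other list medians these had no CPM minimum, left out genes with 0 UMIs in both libraries and rest partly on genes with few UMIs (Arntl with 0 and 2 in AT1-like cells), so their sizes are uncertain. Per2 and Per3 went against the direction of the Dbp phase list in AT2-like cells (0.848 and 0.945 times the control level). A link from the clock to the fatty acid oxidation genes was not tested. With 1 library per group, an effect of the tumor cannot be told apart from a difference between mice, hours of sampling or libraries.

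Lower MHC class I genes in AT2-like cells were weighed in the same way. B2m, which has no close paralog, lay at -0.85 relative to all genes, which argues against reads shared between H2 paralogs, and subtracting free RNA left the list median at -0.25. Another mix of clusters stays open. The list median was -0.072 in the cluster led by Areg, Gsta1 and MHC class II genes, but -0.30 to -0.24 in the other 3 large clusters. Within all 4, B2m lay between -0.89 and -0.38 and H2-K1 between -0.73 and -0.54. The uneven cell numbers of these clusters limit this comparison as well. Outside these clusters the list median was -0.245 in ciliated-like cells. In AT1-like cells it was -0.199, near the -0.18 of all their genes. A weaker interferon signal stays open too, because the interferon median was 0.20 and changed sign between settings. The tumor as the cause may hold, but 1 mouse per group cannot show it.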
